A study of Mus musculus with 2 samples.

How the data were processed

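RNA was sequenced from mouse bone-marrow-derived macrophages stimulated for 120 minutes, in 2 libraries of 1 group, with 1 µg of starting RNA and a size range of 250 to 400 per the labels. Groups and replicate numbers were taken from the labels. For each library the authors deposited a gene table and 2 transcript tables. Per the file headers, the gene table and the first transcript table hold expected counts, TPM and, for transcripts, the percent of a gene's TPM in each transcript, under the column names that RSEM writes. The second transcript table holds estimated counts and TPM under the column names that kallisto writes, per the file headers. Per the deposited descriptions the first 2 tables came from a transcriptome alignment and the third from 4 read files and an index, with assembly mm10 and GENCODE annotation M21. Program versions and whether the counting used strand were not given in the sources used here. TPM divides by transcript length, so very short genes weigh more in it than in counts. Without a stated strand, reads of antisense partners such as Xist and Tsix cannot be told apart.

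The gene table held 81881 entries, of which 55536 were mouse genes, 96 were ERCC spike-in entries, 26248 were tRNA entries and 1 was the phiX control genome. ERCC and tRNA entries had 0 counts in both libraries, and phiX held 0.141% and 0.134% of counts. These entries were left out of library sizes and ratios. Symbols were matched for 55450 gene identifiers, and the other 86, with 0.0120% and 0.00961% of counts, were left unnamed. The reference annotation was of the same build, mm10, and gave coordinates and transcript types. Total counts were 33319563 and 50334059, and 37025251 and 57832556 in the second quantification. Intervals are exact Clopper-Pearson binomial intervals at 95%, and like the floors of 3 counts they cover counting error only, since reads without molecular identifiers are not independent molecules.

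Expected counts were rounded to whole numbers. The spread between replicates was the square root of the common dispersion from edgeR 4.0.16 (R 4.3.3) with an intercept alone and TMM factors, over genes with 10 counts or more in both libraries. Ratios between replicates used TMM-normalised CPM for genes with a mean count of 50 or more, and the identity of the libraries was tested by chi-square. List medians used log2 of TPM + 1, which understates the ratio of low genes, over members at 1 TPM or more on average. Each was set against 10000 random lists of the same size drawn in 20 bins of mean TPM, for lists with at least 5 such members. The second transcript table was summed by gene. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and Biopython 1.88 were used for the rest, and matplotlib 3.10.9 for the plots.

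The design, the 27 gene lists with 432 genes, all found, and the alternatives were fixed before the data were examined. The genes named in the text are, in each list, the 4 with the highest mean TPM and the one with the largest absolute log2 ratio at a mean count of 50 or more. To these were added 18 genes named in advance such as Tnf and Gapdh, the 20 most abundant genes, the 8 furthest higher and 8 furthest lower in replicate 2, and the 12 list genes with the lowest leading share. Genes outside this rule are said to be so. Of symbols with more than 1 identifier the one with more counts was kept. The tests were tried on simulated libraries drawn from real means with the measured spread. Over 10445 genes, 195 of 200 genes changed 4-fold were recovered at 2-fold or more, and over 12178 genes a coefficient of variation of 21.5% was recovered as 0.216. In a first run 7 of 40 unchanged lists of 20 genes fell outside the central 95% of random lists, more than the 5% intended. A second run, added because of the first, gave 23 of 400, or 5.75%, and both runs are kept here.

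Alternatives were DESeq2 1.42.0 size factors, other count and TPM minimums, other pseudocounts and bins, TPM without mitochondrial genes, posterior mean TPM, the second quantification and each replicate alone. Added after the data were seen were TPM without nuclear rRNA genes and list ratios with the trend on transcript length and GC content removed. No conditions were compared, because the labels give 1 group.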

Results

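Bone-marrow-derived macrophages of C57BL/6J mice, primary cells grown out of marrow, were stimulated with 100 ng/ml lipid A for 120 minutes and their polyadenylated RNA was sequenced. Lipid A is the membrane anchor of bacterial lipopolysaccharide and the part that the receptor Tlr4 senses. The labels disagree on the stimulus: the free-text description names lipid A, and the treatment and source fields name a protein, lipoprotein A. The series holds 1 group of 2 libraries, numbered as biological replicates 1 and 2, which carry the same donor record, so separate animals are not stated. The gene tables held 33319563 estimated counts for replicate 1 and 50334059 for replicate 2. At these depths 3 counts, the limit that a count of 0 allows, correspond to 0.0902 and 0.0597 CPM, counts scaled to library size, for counting error only. No unstimulated libraries were analysed here, so each value below is a level in stimulated cells and not a response to the stimulus. Values with ± are means and SD with n = 2, and TPM is the abundance scaled to transcript length and library size.

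Macrophage identity genes were among the most abundant mRNAs and summed to 89864 and 93256 TPM in replicates 1 and 2. Lyz2, which encodes lysozyme, stood at 16400.3 ± 4077 TPM (SD, n = 2), the lysosomal protease gene Ctsd at 11409.7 ± 1285 TPM, the glycoprotein gene Gpnmb at 12469.6 ± 477 TPM and the apolipoprotein gene Apoe at 11268 ± 708 TPM. The ferritin genes Fth1 and Ftl1, for iron storage, reached 21272 ± 3482 TPM and 19146 ± 88.6 TPM. Csf1r, the receptor for the macrophage growth factor, stood at 678 ± 71.1 TPM, and Adgre1, which encodes the F4/80 antigen, at 694 ± 18.6 TPM. Of 31 macrophage identity genes, 30 were at 1 TPM or more in both replicates and 23 at 100 TPM or more, with a median of 772 TPM. The transcription factor gene Cebpa was the member furthest apart, at 12.4 and 5.96 TPM in replicates 1 and 2. Other genes among the 20 most abundant were Psap (13388 ± 588 TPM) and Ctsb (10912 ± 342 TPM) of the lysosome, B2m (7446 ± 362 TPM) of MHC class I, the actin-binding Tmsb4x (5799.9 ± 1165 TPM), Selenop (5647 ± 1358 TPM), Eef1a1 (5287 ± 732 TPM) and Lgals3 (5212 ± 1085 TPM). In all, 10285 genes were at 1 TPM or more in both replicates, of which 9596 were protein coding.

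Markers of other cell types were mostly near the floor, with exceptions. Among granulocyte markers, S100a9 and S100a8, which encode the calprotectin subunits, stood at 266 and 41.2 TPM and 167 and 20.5 TPM in replicates 1 and 2, and the granule protein gene Ngp at 67.5 and 3.21 TPM. The platelet chemokine genes Pf4 and Ppbp stood at 916 and 236 TPM and 13.9 and 1.55 TPM. Of 14 granulocyte markers 6 were at 1 TPM or more in both replicates, the colony-stimulating factor receptor gene Csf3r among them at 39.8 ± 7.71 TPM (SD, n = 2), and of 6 megakaryocyte and platelet markers 2 were. T cell markers passed that level in 3 of 9 cases, Cd28 at 108 ± 4.86 TPM, the coreceptor gene Cd4 at 72.7 ± 3.42 TPM and the kinase gene Lck at 7.48 ± 4.07 TPM, while Cd3g had 3 and 0 counts in replicates 1 and 2. B cell markers passed in 3 of 8 cases, led by the inhibitory receptor gene Cd22 at 18.4 ± 0.849 TPM and Ighm at 9.52 ± 0.891 TPM. None of the 7 NK cell markers, 9 mast cell and basophil markers or 8 stromal markers was at 1 TPM in both replicates. Dendritic cell markers passed in 2 of 9 cases (Batf3 at 4.0 ± 0.375 TPM and Ccr7 at 1.70 ± 0.594 TPM), and 1 of 10 erythroid markers did (Epor at 2.68 ± 1.60 TPM). Osteoclast markers passed in 3 of 8 cases, led by the acid phosphatase gene Acp5 at 107 ± 55.9 TPM. Counts of these markers depend on the level asked for and, for granulocytes, on the library. With each replicate taken by itself, 10 granulocyte markers were at 1 TPM or more in replicate 1 and 6 in replicate 2.

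Inflammatory cytokine and chemokine transcripts were abundant after 120 minutes. Cxcl10, a chemokine gene induced by interferon, stood at 4255 ± 1014 TPM (SD, n = 2), and the chemokine genes Ccl4 and Ccl5 at 4053 ± 768 TPM and 2575 ± 73.6 TPM. Il1b, which encodes interleukin-1 beta, stood at 2694 ± 1199 TPM, and Tnf, the tumour necrosis factor gene, at 1194 ± 602 TPM. The Tnf gene lies on chromosome 17, 35199381 to 35202007, Il1b on chromosome 2, 129364570 to 129371139 and Cxcl10 on chromosome 5, 92346638 to 92348889 (mm10). Il12b, a subunit gene of interleukins 12 and 23, stood at 373 ± 137 TPM, the anti-inflammatory Il10 at 102 ± 36.2 TPM and Il6 at 39.6 ± 4.60 TPM. Of 34 list members, 30 were at 1 TPM or more in both replicates and 18 at 100 TPM or more, with a median of 204 TPM. The member furthest apart was Csf2, the granulocyte-macrophage colony-stimulating factor gene, with 263 and 26 counts in replicates 1 and 2.

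**Figure D1:**
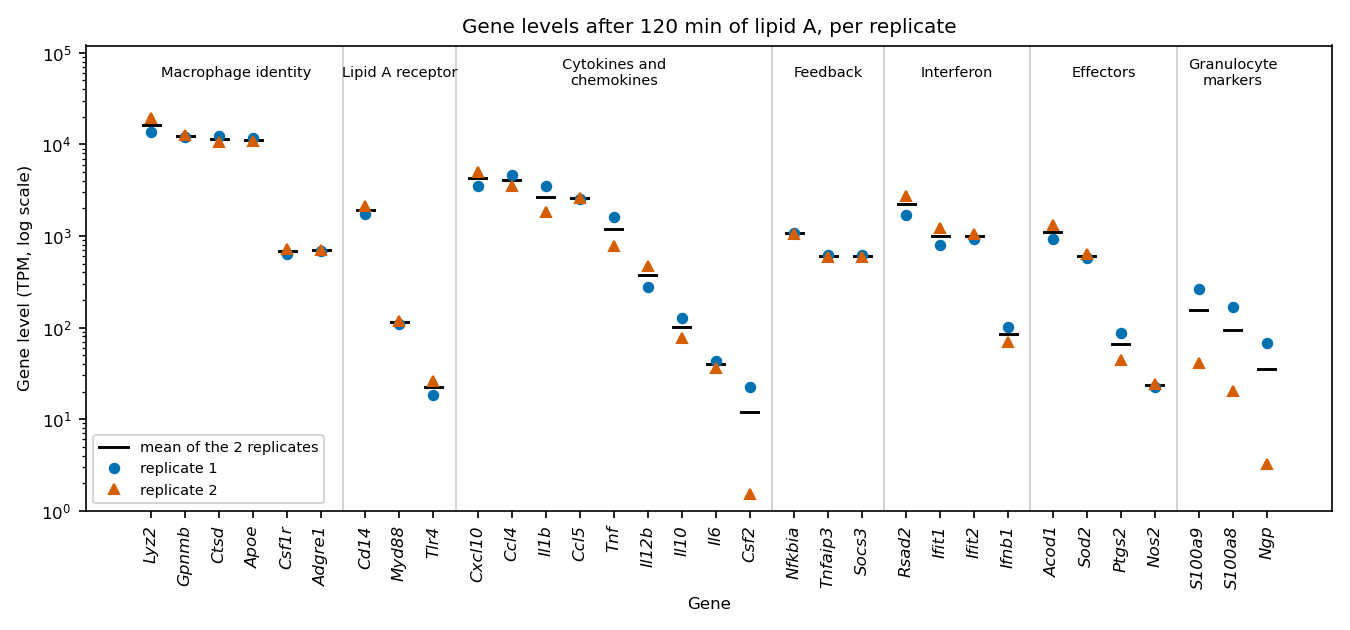
Gene levels in TPM (vertical axis, log scale) for genes of 7 groups (horizontal axis), with replicate 1 as circles, replicate 2 as triangles and their mean as a bar. Lyz2 lies at 16400.3 ± 4077 TPM and Nos2 at 23.5 ± 1.23 TPM (SD, n = 2), and the replicates lie furthest apart for Csf2 and Ngp.

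Feedback regulators of NF-kB and MAPK signalling were all expressed, and the replicates lay close for the most abundant of them. Tnfaip2, a gene induced by tumour necrosis factor, stood at 2114 ± 231 TPM (SD, n = 2), and Nfkbia, which encodes the NF-kB inhibitor IkB alpha, at 1064 ± 23.5 TPM. Tnfaip3, for the ubiquitin-editing enzyme A20, stood at 604 ± 21.5 TPM and the cytokine signalling suppressor gene Socs3 at 603 ± 19.6 TPM. All 25 members were at 1 TPM or more in both replicates, with a median of 164 TPM, and the phosphatase gene Dusp16 was furthest apart at 16.5 and 35.7 TPM in replicates 1 and 2. All 10 genes of NF-kB subunits and kinases passed, with a median of 58.6 TPM, led by Nfkb1 (276 ± 6.41 TPM), Nfkb2 (271 ± 7.27 TPM), Rela (143 ± 5.21 TPM) and Relb (83.9 ± 8.24 TPM), while the kinase gene Map3k14 stood at 5.42 and 10.5 TPM. Immediate-early transcription factor genes passed in 22 of 24 cases with a median of 20.9 TPM, led by Atf3 (466 ± 9.92 TPM), Klf6 (242 ± 4.67 TPM), Junb (200.3 ± 1.46 TPM) and Ier3 (101 ± 49.7 TPM), while Fosl2 stood at 24.6 and 44.4 TPM.

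Interferon-stimulated genes were expressed as a group, and so was Ifnb1. Slfn2 stood at 2267 ± 42.8 TPM (SD, n = 2), Rsad2, which encodes the antiviral protein viperin, at 2211 ± 741 TPM, and the antiviral RNA-binding protein genes Ifit1 and Ifit2 at 1002 ± 289 TPM and 997 ± 84.7 TPM. All 40 members were at 1 TPM or more in both replicates, 28 of them at 100 TPM or more, with a median of 209 TPM. The exonuclease gene Isg20 was furthest apart, at 19.2 and 40.1 TPM in replicates 1 and 2. Ifnb1, the interferon beta gene, stood at 85.5 ± 22.3 TPM, the receptor genes Ifnar2 and Ifnar1 at 174 ± 19.1 TPM and 93.9 ± 14.5 TPM, and the kinase gene Jak1 at 124 ± 11.3 TPM. The list of type I interferons and their receptor had 5 of 10 members at 1 TPM or more in both replicates and a median of 13.3 TPM. Its interferon alpha genes, like several interferon-stimulated families, have close paralogs, so reads can be split among them and those levels are uncertain.

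Transcripts of the lipid A sensing pathway were present, with the coreceptor far above the receptor. Cd14, the coreceptor gene, stood at 1927 ± 279.7 TPM and Tlr4 at 22.2 ± 5.63 TPM (SD, n = 2). The adaptor gene Myd88 stood at 114 ± 5.16 TPM, the transcription factor gene Irf5 at 179 ± 14.6 TPM and the kinase gene Ikbke at 121 ± 17.5 TPM. Of 21 members 20 were at 1 TPM or more in both replicates, with a median of 28.7 TPM, and the lipopolysaccharide-binding protein gene Lbp was furthest apart at 1.42 and 0.59 TPM in replicates 1 and 2. Other pattern receptor and inflammasome genes passed in 22 of 25 cases with a median of 57.3 TPM. They were led by the lectin receptor genes Clec4d (1052 ± 0.523 TPM), Clec7a (491 ± 29.3 TPM) and Clec4e (484 ± 60.3 TPM) and the lipoprotein receptor gene Tlr2 (822 ± 85.0 TPM). Tmem173, which encodes STING, stood at 13.0 and 26.6 TPM.

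Effector and metabolic genes covered a wide range of levels. Acod1, which encodes the enzyme that makes itaconate, stood at 1113 ± 274 TPM (SD, n = 2), the NADPH oxidase subunit genes Cyba and Cybb at 1632 ± 236 TPM and 487 ± 52.6 TPM, and the mitochondrial superoxide dismutase gene Sod2 at 606 ± 41.9 TPM. Nos2, for inducible nitric oxide synthase, stood at 23.5 ± 1.23 TPM, and Ptgs2, for cyclooxygenase-2, at 88.0 and 44.0 TPM in replicates 1 and 2. All 24 antimicrobial and oxidative effector genes were at 1 TPM or more in both replicates, with a median of 121 TPM, and the urokinase gene Plau was furthest apart at 119 and 26.2 TPM. All 19 glycolysis genes passed with a median of 139 TPM, led by Gapdh (1318 ± 119 TPM), Aldoa (559 ± 41.2 TPM), Pkm (428 ± 42.6 TPM) and Ldha (326 ± 72 TPM), while the lactate transporter gene Slc16a3 stood at 13.7 and 20.4 TPM. The actin gene Actb stood at 4073 ± 1116 TPM. All 16 sterol genes passed with a median of 47.3 TPM, led by the cholesterol exporter gene Abca1 (169.8 ± 25.7 TPM), Insig1 (90.8 ± 46.1 TPM), Nr1h2 (57.7 ± 0.445 TPM) and Srebf2 (57.5 ± 4.69 TPM), while the desaturase gene Scd1 stood at 1.49 and 6.06 TPM. Alternative activation genes passed in 8 of 12 cases with a median of 17.4 TPM, led by Il1rn (771 ± 112 TPM), Mrc1 (254 ± 45.6 TPM), Il4ra (152 ± 52.1 TPM) and Clec10a (39.7 ± 4.24 TPM), while Chil3 stood at 27.1 and 12.1 TPM.

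Antigen presentation genes were abundant and most cell cycle genes were low. B2m and the MHC class I heavy chain genes H2-D1 and H2-K1 stood at 7446 ± 362 TPM, 3804 ± 709 TPM and 3527 ± 102 TPM (SD, n = 2). The adhesion molecule gene Icam1 stood at 1131 ± 176 TPM, and the costimulatory gene Cd86 at 34.7 and 71.8 TPM in replicates 1 and 2. All 19 members were at 1 TPM or more in both replicates, with a median of 225 TPM. H2-D1 and H2-K1 are close paralogs that can share reads, so their levels are uncertain. Cell cycle genes passed in 15 of 22 cases with a median of 5.46 TPM, but the median depended on the library, at 7.93 TPM in replicate 1 with all 22 at 1 TPM or more and 2.68 TPM in replicate 2. Pcna, the replication clamp gene, stood at 284 ± 11.6 TPM, the proliferation marker Mki67 at 37.6 ± 5.66 TPM, the mitotic kinase gene Cdk1 at 22.6 ± 9.91 TPM and the replicative helicase gene Mcm6 at 21.1 ± 5.23 TPM, while the cyclin gene Ccnb2 had 140 and 21 counts in replicates 1 and 2.

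The only comparison that the labels allow is replicate 2 against replicate 1. Csf2, Lif, Chil1, Ltf, Ngp, Ccnb2, Cenpf and Pagr1a were the 8 genes furthest lower in replicate 2, among genes with a mean count of 50 or more. Their log2 ratios of CPM normalised by TMM (trimmed mean of M-values) were -3.79 for Csf2, -3.19 for the cytokine gene Lif, -4.68 for the chitinase-like gene Chil1, -4.28 for the lactoferrin gene Ltf, -4.28 for Ngp, -3.18 for Ccnb2, -3.13 for the kinetochore gene Cenpf and -3.55 for Pagr1a. The endothelial lipase gene Lipg had 825 and 6506 counts in replicates 1 and 2, a log2 ratio of 2.53. The adenosine receptor gene Adora3 (2.59), the metalloreductase gene Steap4 (3.04), the prostaglandin receptor gene Ptger3 (3.51) and Fxyd2 (3.60) were also among the 8 furthest higher. Lrrc14b had 3 and 311 counts, and the mitochondrial genes mt-Co3 and mt-Co2 had 1 and 1840 counts and 139 and 1164 counts. The chromosome 1 copies Gm28437 and Gm28661 match mt-Co3 and mt-Co2 over 783 and 681 bases without a difference. These copies held 83699 and 125071 counts and 104622 and 97089 counts, so the ratios of mt-Co3 and mt-Co2 are uncertain.

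Across 10445 genes with a mean count of 50 or more, 85.4% lay within 1.5-fold of each other and the median absolute log2 ratio was 0.24. At 2-fold or more apart were 414 genes (3.96%), of which 181 were higher and 233 lower in replicate 2. On the TPM + 1 scale 230 genes were, 66 higher and 164 lower, and with a mean count of 200 or more 186 were, 109 higher and 77 lower. The biological coefficient of variation from edgeR was 21.5% over 12178 genes, and in simulated libraries with that spread 2.92% of unchanged genes lay 2-fold or more apart. A chi-square test of the 2 libraries' counts gave 120.8 per degree of freedom with 12177 degrees of freedom, more than sampling noise gives for 1 library deposited 2 times. It does not show that they came from separate cultures, so the spread with n = 2 may be technical. Across 11121 genes, which are not independent replicates, log2(TPM + 1) values had a Pearson r of 0.975 and a Spearman rho of 0.973. With 1 library on each side no gene has a replicate check, and no p-value is given for any gene.

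**Figure D2:**
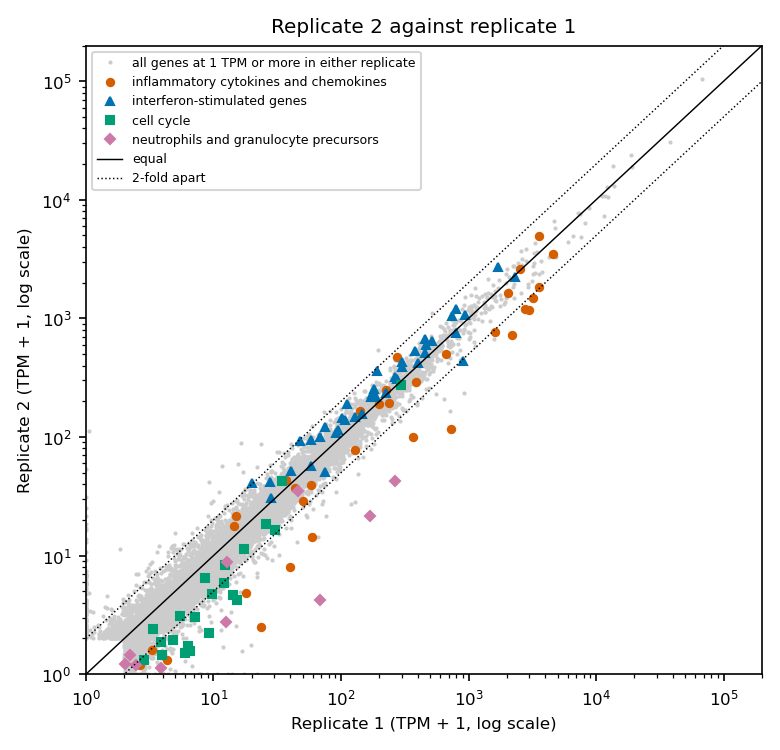
Replicate 2 against replicate 1 in TPM + 1 (both axes log scale), each point a gene at 1 TPM or more in either replicate, with members of 4 gene lists in colour. The solid line marks equal values and the dotted lines 2-fold differences, and all 7 granulocyte markers tested lie below the solid line.

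Cytokine, cell cycle and granulocyte genes were lower in replicate 2, and interferon-stimulated genes were higher. The cytokine and chemokine list had a median log2 ratio of -0.65 (replicate 2 over replicate 1, TPM + 1), with 24 of 32 members lower and 13 lower by 2-fold or more. Il1b stood at 3541 and 1846 TPM, Tnf at 1619.6 and 768 TPM and Il10 at 127 and 76.0 TPM in replicates 1 and 2, while Cxcl10 (3538 and 4972 TPM) and Il12b (276 and 469.7 TPM) went the other way. The cell cycle list had a median of -1.05 with 21 of 22 members lower, Mki67 (33.6 and 41.6 TPM) being the exception, and the granulocyte list a median of -2.17 with 7 of 7 lower. The interferon-stimulated list had a median of 0.35 with 35 of 40 members higher, among them Rsad2 (1686 and 2735 TPM) and Ifit1 (797 and 1206 TPM). None of 10000 random lists of the same size, matched on mean TPM, had a median as low as the first 3 or as high as the last. In the same libraries nuclear rRNA genes held 6.82% and 10.5% of TPM and mitochondrial genes 7.12% and 5.64%.

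Of the 16 lists tested in this way, 6 lay outside the central 95% of random lists. Besides the 4 above, these were pattern receptor and inflammasome genes, with a median of 0.17 and a percentile of 99.7, and sterol genes, with a median of 0.11 and a percentile of 97.7. The second quantification put the median log2 ratio of the 10445 genes at -0.19, against -0.09 for the first, and the medians of these lists at -0.01 and -0.01, still above the random lists at percentiles of 98.5 and 98.0. The sterol list was within the random range among members at 5 TPM or more, at a percentile of 95.5. The remaining 10 lay within it: feedback regulators (-0.05), NF-kB subunits and kinases (0.01), immediate-early factors (0.06), type I interferons and their receptor (-0.16), the lipid A receptor and adaptors (0.08), effectors (-0.03), macrophage identity (0.02), alternative activation (-0.16), glycolysis (-0.18) and antigen presentation (0.10). On the TMM scale the immediate-early and antigen presentation lists passed to percentiles of 97.52 and 97.9. The sex-linked list and the marker lists other than that of granulocytes, 11 lists together, had too few members to test. These percentiles describe the libraries and say nothing of other cultures.

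**Figure D3:**
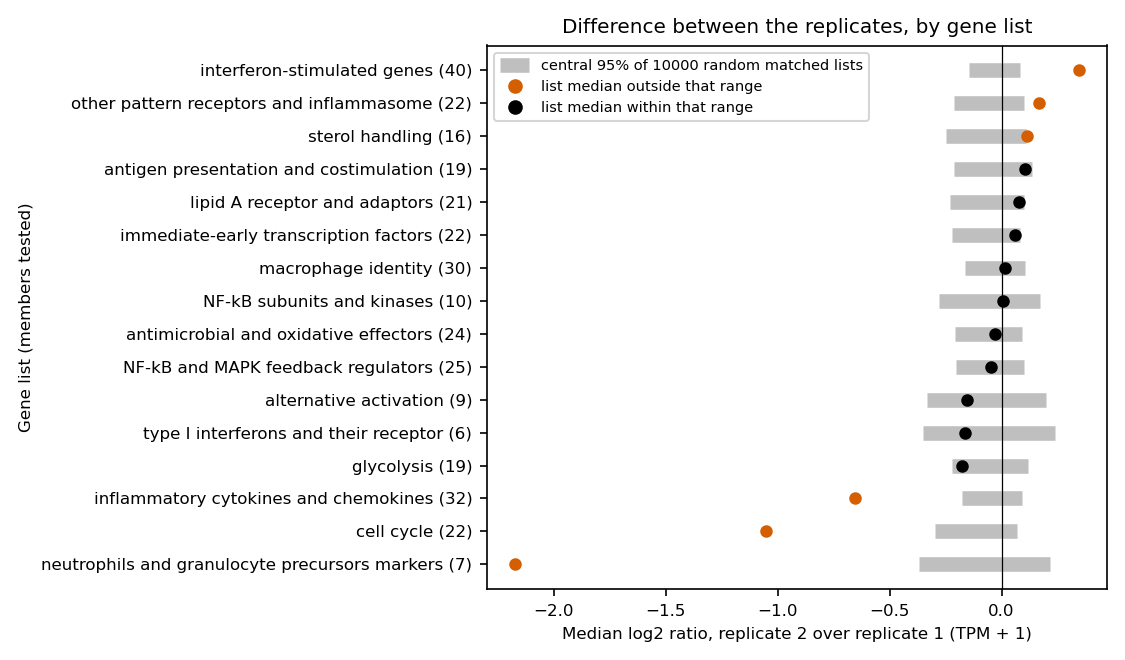
Median log2 ratio of replicate 2 over replicate 1 in TPM + 1 (horizontal axis) for 16 gene lists (vertical axis, with the members tested), as points over grey bars for the central 95% of 10000 random matched lists. The medians run from -2.17 for granulocyte markers to 0.35 for interferon-stimulated genes, and 6 lie outside their bar; the second quantification puts the pattern receptor and sterol medians at -0.01 and -0.01.

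Most expressed list genes had 1 leading transcript. Among 244 list genes at 20 TPM or more, 212 had more than 1 annotated transcript, and the leading one held a median of 84.7% of the gene's TPM. It held over 90% in 91 genes and under 50% in 24. The lowest shares were 29.1% ± 3.33 (SD, n = 2) for the signalling adaptor gene Traf1, 33.6% ± 4.64 for Sod2, 33.8% ± 4.49 for the costimulatory receptor gene Cd40, 35.9% ± 2.32 for the interferon regulatory factor gene Irf7 and 35.9% ± 3.60 for the MHC class II gene H2-Eb1. They were followed by Pfkfb3 (36.4% ± 10.6), Mx1 (39.9% ± 4.48), Nlrc5 (42.2% ± 8.76), Clec7a (42.4% ± 0.88), Il18 (43.5% ± 2.86), Aim2 (43.8% ± 4.17) and Nr1h2 (43.9% ± 0.646). The leading transcripts of Sod2, Traf1 and Aim2 were annotated as processed transcripts without a coding sequence, those of H2-Eb1 and Nlrc5 as retained introns, and that of Mx1 as subject to nonsense-mediated decay. The second quantification named the same leading transcript for 200 of the 212 genes and another one for 12, Traf1, Pfkfb3, Mx1, Nlrc5 and Clec7a among them. In it the transcripts that led in the first held 24.0% for Traf1, 3.59% for Pfkfb3, 12.1% for Mx1, 28.2% for Nlrc5 and 35.1% for Clec7a.

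A single ribosomal RNA gene and mitochondrial sequence took a large part of the TPM. The rRNA gene CT010467.1, on chromosome 17, 39846353 to 39848827 (mm10), stood at 68159 and 105185 TPM in replicates 1 and 2, and nuclear rRNA genes held 6.82% and 10.5% of TPM. Mitochondrial genes held 7.12% and 5.64%, ribosomal protein genes 6.40% and 7.29%, histone genes 0.0337% and 0.0442%, and the 20 most abundant genes 29.1% and 32.0%. Leading the mitochondrial genes in the first quantification were mt-Atp8 (34234 ± 5001 TPM, SD, n = 2) and mt-Co1 (8671 ± 251 TPM). There mt-Atp6 stood at 64.4 and 80.1 TPM in replicates 1 and 2, against 5443 and 3832 TPM in the second quantification. Nuclear copies of mitochondrial genes on chromosome 1, between 24612407 and 24616197 (mm10), held 4.10% and 3.14%, led by Gm28661 (9494 ± 3030.4 TPM), Gm28437 (7486 ± 90.2 TPM), Gm10925 (7224 ± 1279 TPM) and Gm28438 (6188 ± 1945 TPM). Gm28437, Gm28661 and Gm10925 matched mt-Co3, mt-Co2 and mt-Atp6 over 783, 681 and 678 bases without a difference, so the split of reads between them is uncertain. By estimated counts, which leave out transcript length, mitochondrial genes held 1.83% and ribosomal protein genes 1.78% on average.

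The 2 quantifications of the same libraries ranked genes alike but disagreed on some. Over 11980 genes at 1 TPM or more in either, the Spearman rho across genes was 0.927 for replicate 1, and over 11514 genes it was 0.925 for replicate 2, with Pearson r of 0.919 and 0.915. Levels lay 2-fold or more apart for 1351 and 1232 genes, and for 201 and 220 with a mean count of 50 or more. Of the 1351, 1020 were higher and 331 lower in the second quantification, and of the 1232, 854 and 378. Among genes with a symbol that lay 2-fold or more apart in both libraries with a mean count of 50 or more, 77 were processed pseudogenes and 51 protein coding. Of these, 69 and 30 were lower in the second quantification. Other classes at this minimum were mostly lower too, such as antisense genes (6 of 9) and transcribed processed pseudogenes (7 of 10). The counts over all genes, mostly higher, had no count minimum, so the change of direction is not particular to a class. The next 3 genes were chosen after their values were seen. The zinc finger factor gene Klf10 stood at 5.71 and 2.77 TPM in replicates 1 and 2 in the first and 1254 and 809.7 TPM in the second. With a smaller gap, the mitochondrial leucyl-tRNA synthetase gene Lars2 stood at 259 and 336 TPM and 1543 and 2474 TPM. In the other direction, the pseudogene Gm10222 stood at 2948 and 1836 TPM in the first and 0 TPM in both libraries in the second. The mitochondrial gene mt-Atp8 averaged 34234 ± 5001 TPM (SD, n = 2) in the first and 7079.6 TPM in the second.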

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

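Both libraries held reads of the phiX genome, a control for sequencing runs that is outside the mouse measurement, and its counts were above the 3 that a count of 0 allows. Replicate 1 had 46982 phiX counts, 0.141% of all counts (exact 95% interval 0.140% to 0.142%), and replicate 2 had 67656, 0.134% (0.133% to 0.135%). The 96 ERCC spike-in entries of the same tables had 0 counts in both libraries.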

How the results depend on the processing

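Values without nuclear rRNA genes and with the length and GC trend removed were computed after the results were seen. The trend was removed from ratios of TMM-normalised CPM, so a change with the trend removed is not separate from one on the TMM scale. The cytokine, cell cycle, granulocyte and interferon-stimulated lists kept their direction and their side of the random lists under every alternative run, and the coefficient of variation ranged from 0.192 to 0.235. The number of genes 2-fold apart was 230 on the TPM + 1 scale, 1044 at a mean count of 10 and 186 at a mean count of 200. With the second quantification the pattern receptor list (-0.0069) and the sterol list (-0.0054) had medians of the other sign, where the median of all genes also lay lower, at -0.19, and 5 lists with medians near 0 changed sign too. The feedback regulator list, also near 0, changed sign on the TMM scale (0.06) and with the trend removed (0.11), and the effector list on the TMM scale (0.07), among members at 5 TPM (0.02) and with the trend removed (0.05). The sterol list came within the random range among members at 5 TPM (median 0.10) and with the trend removed (0.20), and the cause was not tested. The immediate-early list left it on the TMM scale (0.18) and with the trend removed (0.24), as did the antigen presentation list (0.24 and 0.29), and the cause was not tested.

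Marker counts followed the level asked for. At 0.1 TPM in both replicates there were 9 type I interferon and receptor genes, 12 granulocyte, 9 dendritic cell, 1 mast cell, 4 megakaryocyte, 4 stromal, 4 endothelial and 5 osteoclast markers. At 5 TPM there were 7 cell cycle genes and 0 dendritic cell, 0 erythroid, 1 megakaryocyte and 1 endothelial marker, and the second quantification gave 1 dendritic cell marker. Leaving out each replicate in turn gave 6 to 10 granulocyte markers, 2 to 4 dendritic cell markers, 1 mast cell marker either way and a median leading transcript share of 84.4% to 85.9%. That share was 83.5% for genes at 5 TPM. Genes 2-fold apart between quantifications were 473 and 470 at 5 TPM, and 201 and 220 at a mean count of 50. By share of counts and by the second quantification, mitochondrial genes held 1.83% and 4.23%, ribosomal protein genes 1.78% and 4.56%, histone genes 0.0221% and 0.0291%, and the 20 most abundant genes 23.4% and 23.3%, the former because counts leave out transcript length. Of 160 named genes, 14 moved by over 1.5 times in the second quantification, 19 as posterior means, 4 without mitochondrial genes and 1 without nuclear rRNA genes. With 1 replicate left out, 46 to 48 did, and so did 5 to 10 of the 27 list medians, cell cycle among them. No paired analysis was possible because the series holds 1 group.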

Other observations

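The tests below address patterns found in these data and were all chosen after those patterns were seen. A bound called set beforehand was set before the value of its own test was seen. The tests on the S100a8 and S100a9 share, the immediate-early list and the summed mt-Co3 counts had their bounds written after the results were seen. The bootstrap intervals on granulocyte genes and the use of random lists to judge the length and GC tests were also chosen after the results were seen.

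Single endothelial markers differed between the replicates in both directions, and their list was too short at 1 TPM to test. Vwf, which encodes the clotting protein von Willebrand factor, stood at 11.8 and 25.9 TPM in replicates 1 and 2 and Kdr, a receptor gene for vascular endothelial growth factor, at 3.85 and 9.76 TPM, while the endothelial genes Cdh5 (0.74 and 1.22 TPM) and Pecam1 (0.64 and 0.36 TPM) were near 1 TPM or under. Of 6 endothelial markers 2 were at 1 TPM or more in both replicates. Xist, the X-inactivation RNA gene, stood at 69.5 and 33.2 TPM. In the first quantification the other 5 of the 6 sex-linked genes, Ddx3y and Eif2s3y of the Y chromosome among them, had 0 counts in both libraries. A count of 0 allows up to 0.0902 and 0.0597 CPM. The second quantification put the median of the 6 genes at 0.089 TPM, against 0 in the first, so members other than Xist were above 0 there. The stem cell factor receptor gene Kit, in the mast cell and basophil list, stood at 0.57 and 2.53 TPM, and the basophil protease gene Prss34 had 27 and 1 counts.

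Cytokine genes were lower and interferon-stimulated genes higher in replicate 2. On TMM-normalised CPM, removing the trend with transcript length and GC content took the gap between the list medians from 1.01 to 0.91 log2 units. That is above the bound of 0.5 set beforehand, and the lists stayed at percentiles 0 and 100 of random lists. Both argue against such a bias as the whole cause, although the bootstrap interval over genes (0.45 to 1.55) reached below the bound. Granulocytes in the replicate 1 culture stay open as a candidate source. The cytokine list held 10192 TPM less in replicate 2, 27.5 times the 371 TPM by which S100a8 and S100a9 were lower. That met the bound against this source, over 5 times, which was written after the results were seen. The bound cannot decide, because how much cytokine RNA such cells would bring was not measured. A later point of the response in replicate 2 is another candidate explanation, under which immediate-early genes would be lower too. The list of immediate-early transcription factors lay at the 95.4 percentile of random lists, within their central 95%. It lay above that range at 97.52 on the TMM scale and 99.39 with the length and GC trend removed, also from TMM-normalised CPM. Those 2 values argue against a later point only under that assumption, and as the call also depends on the scale this stays open.

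The granulocyte list was lower in replicate 2, and so were the platelet genes Pf4 (916 and 236 TPM) and Ppbp (13.9 and 1.55 TPM). Only these 2 of 6 megakaryocyte and platelet markers were at 1 TPM or more in both replicates, and their list was not tested. On TMM-normalised CPM, the 7 granulocyte list members had a median of -2.92 with the length and GC trend removed, against -2.91 before. That is past the bound of -1 set beforehand and at percentile 0 of random lists, which argues against that bias as the whole cause. However, the bootstrap interval over so few genes was wide (-4.29 to -0.48) and reached above that bound. A larger share of granulocytes in the replicate 1 culture may account for the difference, but 11 granulocyte genes outside the lists had a median log2 ratio of -0.41 (95% bootstrap interval -1.24 to -0.09), with 9 lower and 3 lower by 2-fold or more. That interval spans both bounds set beforehand, -1 and -0.5, and the genes include Anxa1 (741 and 517 TPM) and Hvcn1 (121 and 107 TPM), which macrophages also express, so this stays open. By the median alone it would have been argued against.

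The gene mt-Co3 had 1 and 1840 counts in replicates 1 and 2. Summed with its identical copy Gm28437 on chromosome 1, the counts were 83700 and 126911, a log2 ratio of 0.15 after scaling. The copy held nearly all of these counts and so fixed that ratio, which decides nothing. The second quantification gave mt-Co3 1293 and 1462 TPM. Whether reads shared with the copy were divided differently in the libraries stays open.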
